A study of Mus musculus with 15 samples.

How the data were processed

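The series holds bulk RNA sequencing of 15 mouse samples: 9 of organoids grown from gut (3 labelled Tamoxifen, 3 DMSO and 3 nativ) and 6 of gut tissue (3 described as ctr and 3 as PG_KO). Per the labels, RNA was isolated with TRIZOL, had integrity numbers of at least 7.7, and was enriched for poly(A) RNA with oligo-dT beads before TruSeq library preparation. The labels give 300 ng of input for 4 samples and about 200 ng for 2 without saying which.

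The deposited values are expected counts, that is reads per gene that are not scaled between libraries, 1 table for organoids and 1 for gut, each with 45905 genes. Per the labels, the authors used bcl2fastq 2.20.0.422, cutadapt 2.5, STAR 2.7.2b, featureCounts 1.6.4 from Subread, and DESeq2, on the build GRCm38.p6. The strand setting, read filters and DESeq2 design are not given. Between 10.4% and 13.7% of the values of a library are not whole numbers (any fractional part counted), so reads that match more than 1 gene or place were divided among them, and members of gene families with near-identical copies cannot be told apart. Values were rounded to whole reads before model fits. Symbols, positions and biotypes were taken from the deposited tables, in which 2 symbols occur more than once. Totals per library were 25185053 to 30744563 reads in organoids and 23194385 to 29257641 in gut, and the 10 most abundant genes took 4.94% to 7.52% and 4.47% to 7.79% of them. Depth therefore differed little between libraries, and 3 reads in a library correspond to about 0.1 CPM.

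Samples were grouped by their descriptions, because the titles of the gut libraries give a conflicting genotype. Comparisons, tests, gene lists and most alternatives were chosen before the data were examined. Organoid groups were compared in 1 fit of all 9 libraries, and gut groups in a fit of the 6 gut libraries. The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr by group, robust dispersion estimates and Benjamini-Hochberg adjustment over all tested genes, and calls were made at an adjusted p under 0.05. Standard errors of log2 changes are the absolute change divided by the square root of F. CPM use library totals, and mean log2 CPM of a list use edgeR values with a prior count of 2. A fold against a group with 0 reads is a lower bound, computed against 3 reads over the group. With 1 to 3 reads the ratio is given with a 95% counting interval. Fitted log2 changes of such genes depend on the prior count and are no bounds, so medians of lists are also given with genes at 0 reads set to their bound.

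Gene lists, 29 in all, cover junctions, p38, the inflammasome, inflammation, epithelial states, epithelial cell types and other cell types of the gut wall. A list was tested when at least 5 of its genes were. The test was camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists of a comparison, which asks whether a list differs from the other genes. Its alternatives were camera with an estimated correlation, and fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes. Lists of fibroblasts, endothelium, B and plasma cells, T and NK cells and neutrophils had fewer than 5 tested genes in organoids and were not tested there.

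Genes named in the text were picked by a rule fixed in advance: Jup, the 10 largest changes in each direction among called genes with a mean of at least 5 CPM in a group and groups that do not overlap (leaving out predicted genes, clones, pseudogenes and antigen receptor segments), and the members of each list with the smallest p, 4 where members were called and 2 otherwise, with Xist and 4 Y-linked genes as a check of the animals. Genes outside it are said to have been chosen after their values were seen. Shared calls of gut and organoids were tested with Fisher's exact test, two-sided, and the difference of the changes with an interaction term in 1 edgeR fit of 12 libraries, which was added after the design was fixed.

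Alternatives were DESeq2 1.42.0, limma-voom, RLE factors, library totals, no low-count filter, a minimum of 1 CPM in 3 libraries, the replicate number as a block, fits of only the 6 compared libraries, and leaving out each library in turn. A stromal covariate, leaving out ctr replicate 1 with PG_KO replicate 3, and lists on library totals were added after the data were seen. The tests were checked on simulated counts with the spread of these data. In organoids edgeR recovered 93% to 96% of genes changed by 1 on the log2 scale, and in gut it recovered 8% of these and 63% of genes changed by 2. DESeq2 recovered 43% and 92% in gut, with 63 false calls against 2 by edgeR. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.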

Results

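Poly(A) RNA from mouse intestine and from organoids grown out of mouse intestine was sequenced in 15 libraries. An organoid is a small epithelial structure kept in culture in a gel with growth factors. The 9 organoid libraries fall into 3 groups of 3, named here by their descriptions as Tamoxifen, DMSO and nativ. The Tamoxifen organoids carry the code T41, and their titles give them a floxed Jup gene together with an inducible Cre recombinase under the villin promoter, which tamoxifen activates in intestinal epithelium. The DMSO and nativ organoids share the code T75, and their titles give the floxed gene without Cre. DMSO is a common solvent for drugs such as tamoxifen, and nativ is read here only as a group name. The 6 gut libraries fall into 2 groups of 3, described as ctr and PG_KO, each library with its own code. Totals ran from 25185053 to 30744563 assigned reads per organoid library and from 23194385 to 29257641 per gut library. At these depths 3 reads in a library correspond to between 0.0976 and 0.129 CPM (counts scaled by the library total), and such floors and counting intervals cover counting error only. Spearman correlations across genes between libraries of the same group lay between 0.986 and 0.998 in organoids and between 0.931 and 0.980 in gut. The labels do not say whether replicates of an organoid group were separate cultures, so each p-value measures only the spread between these samples. Each organoid group carries a single code, so organoid p-values do not measure the spread between codes. The chi-square per degree of freedom between 2 libraries is near 1 for counting error alone. It was 2.21 to 3.72 within the Tamoxifen group, 29.6 to 57.4 within DMSO and 7.99 to 105 within nativ.

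Jup encodes plakoglobin, also called gamma-catenin, a protein of the inner plaque of desmosomes and adherens junctions. The series was set up around its removal from the intestinal epithelium, so its own RNA was examined first. The gene is protein-coding and lies on the minus strand of chromosome 11 from 100368856 to 100397839 in GRCm38.p6. In organoids Jup stood at 70.3 ± 1.20 CPM (SD, n = 3) in the Tamoxifen group, 384 ± 27.8 CPM in the DMSO group and 352 ± 67.2 CPM in the nativ group. It was 5.72-fold lower in Tamoxifen than in DMSO organoids, with a log2 change of -2.52 (SE 0.11, edgeR adjusted p = 1.23e-08). The log2 change against nativ organoids was -2.43 (SE 0.11, edgeR adjusted p = 1.63e-08), and all 3 Tamoxifen libraries lay below all 6 others. DMSO and nativ organoids differed by 0.09 on the log2 scale (SE 0.11, edgeR adjusted p = 0.692), which is within the spread between replicates. In gut, Jup stood at 79.4 ± 3.89 CPM (SD, n = 3) in the libraries described as PG_KO and at 390 ± 97.4 CPM in those described as ctr. All 3 PG_KO libraries, at 75.2, 82.8 and 80.3 CPM, lay below all 3 ctr libraries, at 302, 375 and 495 CPM. The log2 change was -2.29 (SE 0.23), a 4.91-fold difference, which did not pass after adjustment over all genes with edgeR (adjusted p = 0.163). Other settings gave Jup adjusted p-values from 2.42e-14 with DESeq2 to 0.604 in the edgeR fit without PG_KO replicate 2, and without ctr replicate 3 the edgeR value was 0.0329. The labels of the gut libraries conflict, because the titles put the Cre transgene on the libraries described as ctr and place colitis from dextran sodium sulfate (DSS), which injures the colon epithelium, with the floxed genotype on those described as PG_KO. Low Jup went with the descriptions, so the gut groups are named by them, and which animals received DSS is not settled by the labels.

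**Figure D1:**
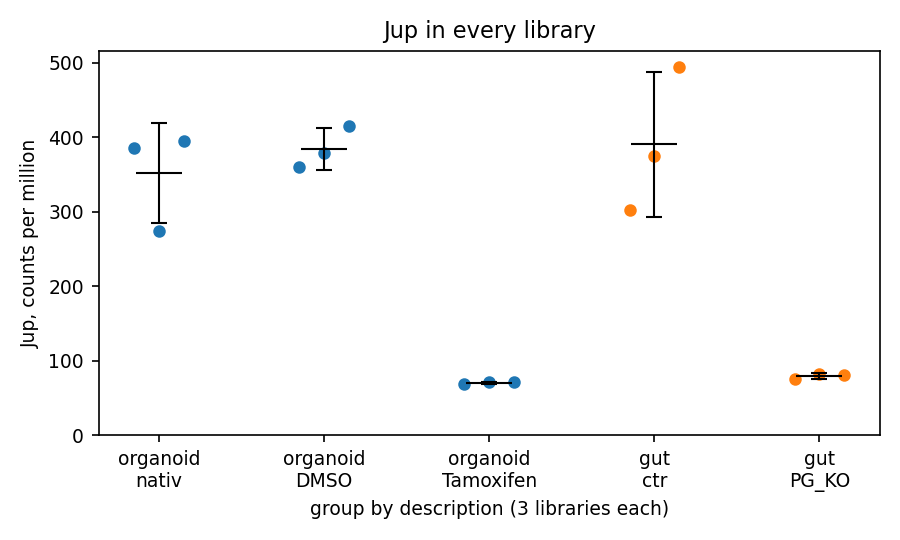
Jup in CPM (vertical axis) in each of the 15 libraries by group (horizontal axis); dots are libraries and the bars show the mean and SD of 3. The Tamoxifen organoids and the PG_KO gut libraries lie between 69.0 and 82.8 CPM, below the other libraries, the lowest of which stands at 275 CPM.

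The comparison of Tamoxifen with DMSO organoids sets organoids with low Jup against organoids with more Jup, although the code and the Cre transgene change along with the treatment. The cultures also differed in Hox genes, which mark position along the gut and were looked at after the results were seen. All Hox genes together stood at 41.1 to 46.4 CPM in Tamoxifen organoids and at 0.119 to 0.262 CPM in DMSO organoids. Camera called the enterocyte, colonocyte, goblet, Paneth and enteroendocrine lists higher in Tamoxifen organoids, of which only the enteroendocrine call stood with an estimated correlation. The tuft cell list was not called (camera adjusted p = 0.619), and its members Ptgs1 and Dclk1 changed by -7.63 (SE 0.24) and -4.86 (SE 0.26). Prap1, a proline-rich acidic protein of the small intestinal epithelium, stood at 377 ± 9.79 CPM (SD, n = 3) against 0 reads, which is at least 10710-fold higher with the floor set at 3 reads over the group. Guca2a, which encodes guanylin, stood at 264 ± 9.09 CPM against 0 reads, at least 7496-fold higher. The DMSO organoids instead expressed Spp1, the secreted phosphoprotein osteopontin, at 2245 ± 62.7 CPM against 0.240 ± 0.0798 CPM, a log2 change of -13.25 (SE 0.26).

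All 18 tested genes of small intestinal enterocytes, the absorptive cells, rose in Tamoxifen organoids with a median log2 change of 11.61 (camera adjusted p = 2.21e-09, adjusted p = 0.264 with an estimated correlation). Among them the fatty acid binding protein Fabp2 changed by 10.25 (SE 0.20) and the apolipoprotein Apob by 10.39 (SE 0.26). All 15 enteroendocrine genes, those of hormone-producing cells, rose with a median of 8.21, or 6.79 with genes at 0 reads set to their bound (camera adjusted p = 2.86e-08, adjusted p = 0.0168 with an estimated correlation). Reg4 and the granin Chgb were at least 3009-fold and at least 3824-fold higher. Of 12 goblet cell genes, which serve mucus secretion, 11 rose and 1 fell, with a median of 7.10 (camera adjusted p = 1.29e-05, adjusted p = 0.208 with an estimated correlation). The trefoil factor Tff3 changed by 11.68 (SE 0.26) and Fcgbp, a mucus protein, by 5.20 (SE 0.10). Of 13 Paneth cell genes 11 rose and 2 fell, with a median of 13.18, or 11.10 with genes at 0 reads set to their bound (camera adjusted p = 9.91e-05, adjusted p = 0.350 with an estimated correlation). Many of these are defensins (Defa genes) whose reads are shared between near-identical copies, so values of single defensins are uncertain. Of 13 colonocyte genes 10 rose and 1 fell, with a median of 8.26 (camera adjusted p = 1.05e-04, adjusted p = 0.127 with an estimated correlation). The gene that fell was Car2, a carbonic anhydrase, at -5.87 (SE 0.17). Of 14 genes of epithelial antimicrobial defence 10 rose and 3 fell, with a median of 5.11 (camera adjusted p = 0.00440, adjusted p = 0.350 with an estimated correlation). The lectin Reg3g rose by 4.90 (SE 0.26), whereas Lcn2, which binds bacterial iron carriers, fell by 11.30 on the log2 scale (SE 0.47).

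Lists of division and metabolism rose as well. All 23 cell cycle genes rose with a median log2 change of 1.57 (camera adjusted p = 6.69e-07, adjusted p = 0.264 with an estimated correlation), among them the replication licensing factor Mcm5 by 2.23 (SE 0.15) and the mitotic kinase Bub1 by 2.27 (SE 0.21). Of 20 genes of cholesterol synthesis 19 rose with a median of 1.47 (camera adjusted p = 7.04e-07, adjusted p = 0.350 with an estimated correlation), such as Hmgcs1 by 1.82 (SE 0.09). Of 23 genes of xenobiotic metabolism 17 rose and 3 fell, with a median of 4.71 (camera adjusted p = 1.29e-05, adjusted p = 0.241 with an estimated correlation). The efflux pump Abcb1a rose by 8.66 (SE 0.17).

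Camera called 4 lists lower in Tamoxifen organoids, of which only the fetal-like and regenerative list kept its call with an estimated correlation. Of 18 genes of fetal-like and regenerative epithelium 15 fell and 2 rose, with a median log2 change of -3.08 (camera adjusted p = 7.72e-07, adjusted p = 0.0170 with an estimated correlation). Clu, a secreted chaperone, stood at 40.7 ± 6.89 CPM in Tamoxifen organoids and changed by -8.01 (SE 0.25). Of 24 interferon response genes 19 fell and 0 rose, with a median of -1.82 (camera adjusted p = 7.21e-05, adjusted p = 0.458 with an estimated correlation). Of 20 inflammatory cytokines and targets of NF-kB 15 fell and 4 rose, with a median of -2.40 (camera adjusted p = 4.59e-04, adjusted p = 0.351 with an estimated correlation). The neutrophil attractant Cxcl5 changed by -8.93 (SE 0.45). Of 15 immediate early and stress genes 12 fell and 1 rose, with a median of -0.81 (camera adjusted p = 0.00529, adjusted p = 0.458 with an estimated correlation). Among single genes that fell were the cadherin Cdh6, at 0 reads against 44.6 ± 5.84 CPM and at least 1319-fold lower, and the transcription factor Sall1, at least 995-fold lower. The mucin Muc1 changed by -12.06 (SE 0.30).

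Genes of the junction, of the p38 kinase and of the inflammasome moved in both directions. Of 10 desmosome genes other than Jup 4 rose and 2 fell (camera adjusted p = 0.678). The desmosomal cadherins Dsc2 and Dsg2 rose by 2.97 (SE 0.21) and 1.38 (SE 0.13), and the plaque protein Ppl fell by 1.99 on the log2 scale (SE 0.14). Of 24 adherens and tight junction genes 11 rose and 6 fell (camera adjusted p = 0.535), and of 7 intestinal keratins 2 rose and 4 fell (camera adjusted p = 0.514), with a median of -0.82 and a mean of 0.24. Of 26 genes of the p38 pathway 6 rose and 11 fell (camera adjusted p = 0.402). The stress-responsive phosphatase Dusp1, which inactivates p38, changed by -3.62 (SE 0.14), Hspb1 by -4.75 (SE 0.28) and the kinase p38 delta, Mapk13, by 1.62 (SE 0.13). Of 19 inflammasome and pyroptosis genes 11 rose and 4 fell (camera adjusted p = 0.0885), with Nlrp6 at 9.86 (SE 0.17), Casp1 at 7.89 (SE 0.29) and Nek7 at -2.83 (SE 0.12). Lists of Wnt targets, p53 targets, tuft cells, smooth muscle, enteric neurons and macrophages had camera adjusted p-values from 0.313 to 0.932, and their members split by direction. The median and the mean differed in sign for Wnt targets, at -0.27 and 0.97, and for macrophages, at -0.35 and 1.62.

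In this comparison 10907 of 16449 tested genes passed an edgeR adjusted p of 0.05, 5571 of them higher and 5336 lower in Tamoxifen organoids, and 5808 of the called genes changed over 2-fold. The groups did not overlap for 76.2% of genes, where chance alone gives 10%. Camera called 13 of 24 lists, the estimated correlation 2 and fry, which asks only whether a list's genes move together, 19. Because T41 and T75, Cre and treatment change together, the difference cannot be assigned to one of them.

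Tamoxifen organoids were then set against the nativ organoids, which share the T75 code and carry no DMSO label. Camera called the same 13 lists, in the same directions. A1cf, a cofactor of RNA editing, stood at 61.4 ± 3.84 CPM (SD, n = 3) against 0 reads, at least 1806-fold higher. Slc27a2, a fatty acid transport protein, was at least 1524-fold higher, and Treh, the brush border enzyme trehalase, at least 785-fold higher. Cdh6 was at least 1048-fold lower, and Spp1 changed by -12.97 (SE 0.26) on the log2 scale. All 18 enterocyte genes rose (median 10.10, camera adjusted p = 4.02e-09, adjusted p = 0.295 with an estimated correlation), as did all 15 enteroendocrine genes (median 8.26, or 6.29 with genes at 0 reads set to their bound, camera adjusted p = 2.67e-08, adjusted p = 0.0166 with an estimated correlation). Of 12 goblet cell genes 11 rose and 1 fell (median 6.59, camera adjusted p = 2.02e-05, adjusted p = 0.180 with an estimated correlation), Tff3 by 11.18 (SE 0.25). Of 13 Paneth cell genes 11 rose and 2 fell (median 11.14, camera adjusted p = 9.98e-05, adjusted p = 0.348 with an estimated correlation), and of 13 colonocyte genes 12 rose and 1 fell (median 8.50, camera adjusted p = 4.71e-05, adjusted p = 0.104 with an estimated correlation). All 23 cell cycle genes rose (median 1.09, camera adjusted p = 1.07e-05, adjusted p = 0.348 with an estimated correlation), Mcm5 by 1.72 (SE 0.15). All 20 cholesterol synthesis genes rose (median 1.61, camera adjusted p = 1.82e-07, adjusted p = 0.348 with an estimated correlation). Of 23 xenobiotic genes 20 rose and 2 fell (median 5.05, camera adjusted p = 1.83e-06, adjusted p = 0.180 with an estimated correlation), and of 14 antimicrobial genes 10 rose and 4 fell (median 5.63, camera adjusted p = 0.0128, adjusted p = 0.357 with an estimated correlation).

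Against nativ organoids 15 of 18 genes of fetal-like and regenerative epithelium fell and 2 rose (median -3.27, camera adjusted p = 1.57e-06, adjusted p = 0.0186 with an estimated correlation), with Clu at -7.83 (SE 0.25). Interferon response genes fell in 19 of 24 cases and rose in 0 (median -2.05, camera adjusted p = 4.45e-05, adjusted p = 0.468 with an estimated correlation). Cytokines and NF-kB targets fell in 15 of 20 cases and rose in 4 (median -2.89, camera adjusted p = 1.90e-04, adjusted p = 0.348 with an estimated correlation), Cxcl5 by 9.51 on the log2 scale. Immediate early and stress genes fell in 12 of 15 cases (median -0.99, camera adjusted p = 0.00269, adjusted p = 0.460 with an estimated correlation). The p38 list, with 8 genes higher and 11 lower of 26, and the inflammasome list, with 11 higher and 5 lower of 19, did not pass (camera adjusted p = 0.340 and 0.0987), and Nlrp6 again stood higher, at 9.41 (SE 0.16). Of 10 desmosome genes 5 rose and 1 fell (camera adjusted p = 0.361), with Dsc2 at 2.92 (SE 0.21) and Ppl at -1.71 (SE 0.14). In all, 11012 of 16449 genes passed an edgeR adjusted p of 0.05, 5506 in each direction, and 5965 of them changed over 2-fold. The groups did not overlap for 74.7% of genes, against 10% by chance. Scaling by library totals alone moved the median log2 change of all genes from 0.01 to 0.13 and gave 6040 higher and 4703 lower. Camera called 13 of 24 lists, the estimated correlation 2 and fry 23.

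**Figure D2:**
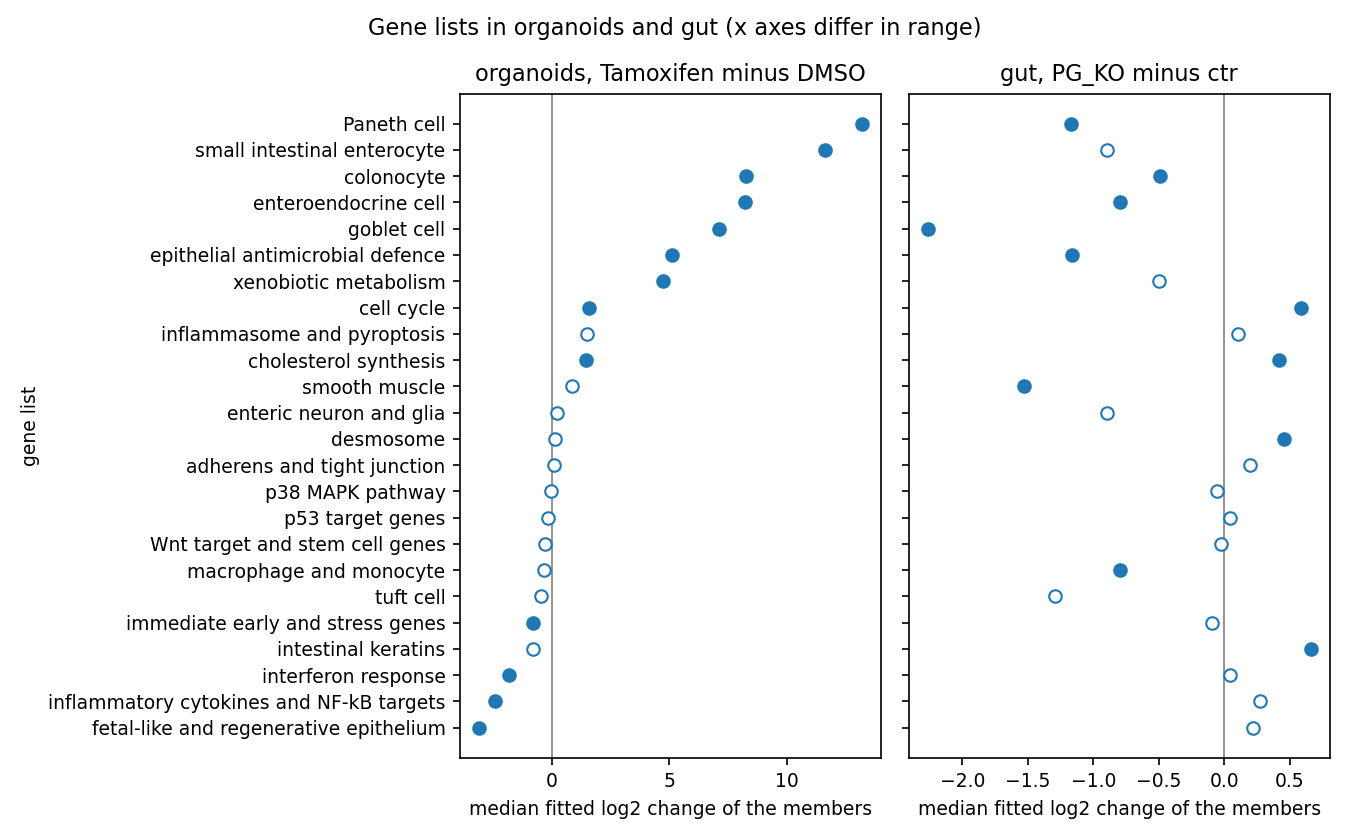
Median log2 change of each of 24 gene lists (vertical axis) in organoids (Tamoxifen minus DMSO) and gut (PG_KO minus ctr), 1 panel each with its own horizontal scale. Filled dots mark a camera adjusted p under 0.05. In the organoid panel the enterocyte, colonocyte, goblet, Paneth and enteroendocrine lists lie far above 0 and the fetal-like and regenerative list lies at -3.08. In the gut panel the medians of these epithelial cell type lists lie between -2.26 and -0.49, and that of the fetal-like list at 0.22.

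DMSO organoids against nativ organoids isolate what the DMSO label stands for, within the same T75 code. Cell cycle genes were lower in DMSO organoids, 22 of 23 of them, with a median log2 change of -0.42, and inflammatory cytokines and NF-kB targets were lower by a median of -0.29, with 17 of 20 negative. The cell cycle median was -0.71 without DMSO replicate 3, and the cytokine median -0.15 without DMSO replicate 1. The survivin gene Birc5 stood at 8.50 ± 1.10 CPM (SD, n = 3) against 16.2 ± 6.03 CPM, and the monocyte attractant Ccl2 at 6.93 ± 1.24 CPM against 13.6 ± 2.60 CPM. The log2 change of Birc5 was -1.01, or -0.56 without nativ replicate 2. With edgeR no single gene passed over all genes, whereas DESeq2 called 157, among them Birc5 (DESeq2 adjusted p = 0.0232) and Ccl2 (DESeq2 adjusted p = 0.00666). Camera called 4 of 24 lists, namely cell cycle (adjusted p = 6.48e-08), cytokines and NF-kB targets (adjusted p = 0.00134), enterocyte (adjusted p = 0.00300) and cholesterol synthesis (adjusted p = 0.0235). All 4 had adjusted p = 0.669 with an estimated correlation, and the lowest fry adjusted p was 0.210. Adjusted over the list alone, 8 cell cycle genes, 5 cytokine genes, 3 cholesterol genes and 0 enterocyte genes passed in the edgeR test. Cholesterol synthesis genes were higher by a median of 0.13 (0.21 without DMSO replicate 3 and 0.077 without nativ replicate 1), with Dhcr7 at 0.41 (SE 0.10, edgeR adjusted p = 0.291, DESeq2 adjusted p = 0.0391). Enterocyte genes were lower by a median of -1.38, or -1.35 at their bounds, with -0.43 without nativ replicate 2 and -0.57 in a fit of only the 6 libraries (camera adjusted p = 0.128). Most of them stood under 1 CPM in both groups. Olfm4, a stem cell marker, stood at 1.10 ± 0.532 CPM against 5.18 ± 2.06 CPM (log2 change -2.29, SE 0.37, edgeR adjusted p = 0.291, DESeq2 adjusted p = 2.04e-06). The inflammasome list (camera adjusted p = 0.456) and the p38 list (camera adjusted p = 0.784) did not pass. Single libraries decided several lists. Nativ replicate 2 stood apart, with a TMM factor of 0.873 and a chi-square per degree of freedom of 105 and 98.7 to the other nativ libraries, which had 7.99 between them. Cholesterol synthesis was lost without DMSO replicate 1 (camera adjusted p = 0.689, median -0.04), without nativ replicate 1 (0.194) or without nativ replicate 3 (0.0609), cytokines without nativ replicate 3 (0.0604), and enterocytes without nativ replicate 2 (0.134). Camera gained the interferon list, lower, without DMSO replicate 3 (adjusted p = 2.38e-05), the desmosome and Wnt lists, higher, without DMSO replicate 1 (0.0263 and 0.0187), keratins, lower, without DMSO replicate 2 (0.0354), and Paneth cells, lower, without nativ replicate 3 (0.0178). In the fit of only the 6 libraries camera gained the xenobiotic list (adjusted p = 0.00172, median 0.47) and the Wnt list (adjusted p = 0.0215, median 0.17), both higher.

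With edgeR, 0 of 16449 genes passed between DMSO and nativ organoids, while 2408 had an unadjusted p under 0.05 where chance gives 822. That count depends on the shared fit of 9 libraries, as the fit of only the 6 compared libraries gave 1198 of 15156 genes. DESeq2 called 157 genes, 88 higher and 69 lower, and limma-voom called 0. The groups did not overlap for 14.1% of genes, against 10% by chance. Without a low-count filter edgeR called Adh1 and 2210407C18Rik, and without nativ replicate 1 it called Lypd8, all 3 lower and chosen after their values were seen.

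The gut comparison asks how intestine with low Jup differs from intestine with Jup. Goblet cell genes were lower in the libraries described as PG_KO: all 14 tested genes had negative log2 changes with a median of -2.26, and the mean log2 CPM of the list was 5.24 ± 0.514 (SD, n = 3) against 7.34 ± 0.186 in ctr. Fcgbp, a mucus protein, stood at 276 ± 108 CPM against 1484 ± 260 CPM. Genes of T and NK lymphocytes were also lower, 13 of 13 with a median of -1.54, and genes of the cell cycle were higher, 23 of 23 with a median of 0.59, or 0.89 without ctr replicate 3. With edgeR no single gene passed after adjustment over all genes, whereas DESeq2 called 458, among them Fcgbp (DESeq2 adjusted p = 1.72e-10). In simulated gut counts more of the DESeq2 calls were false than its threshold allows, so its gut p-values may be too small. Camera called 15 of 29 lists, 4 higher and 11 lower in PG_KO, but the estimated correlation called 0, and fry called only the goblet and Paneth lists (adjusted p = 0.0243 for each).

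The goblet list had a camera adjusted p of 3.47e-10 (adjusted p = 0.327 with an estimated correlation), and adjusted over the list alone 11 of its 14 genes passed in the edgeR test, against 0 over all genes. Its median stayed between -2.47 and -2.07 when each library in turn was left out. Fcgbp changed by -2.43 (SE 0.30, edgeR adjusted p = 0.226), Capn9, a calpain protease of the digestive tract, by -2.95 (SE 0.39) and Retnlb, an antibacterial goblet cell protein, by -3.34 (SE 0.46). Neither Capn9 nor Retnlb passed over all genes in the main edgeR test, but both did with DESeq2 (adjusted p = 1.72e-10 and 5.36e-10) and with edgeR without ctr replicate 3 (adjusted p = 0.0329 and 0.0382). The main gel-forming mucin of the intestine, Muc2, named after its values were seen, stood at 271 ± 156 CPM against 1695 ± 595 CPM. The list of epithelial antimicrobial defence shares Retnlb with the goblet list and, as fixed, Lyz1, Ang4 and Itln1 with the Paneth cell list. It was negative in 14 of 14 genes with a median of -1.17 (camera adjusted p = 5.79e-05, adjusted p = 0.327 with an estimated correlation), and 5 genes passed adjusted over the list alone. The 5 tested Paneth cell genes were all negative with a median of -1.17, or -1.79 without PG_KO replicate 2 (camera adjusted p = 0.00397, adjusted p = 0.327 with an estimated correlation), 3 of them past the edgeR test adjusted over the list alone. Of 16 colonocyte genes 12 were negative, with a median of -0.49, or -0.74 without ctr replicate 1 (camera adjusted p = 0.0184, adjusted p = 0.723 with an estimated correlation) and 2 past the test adjusted over the list alone. That call was lost without ctr replicate 2 (camera adjusted p = 0.0601), ctr replicate 3 (0.511) or PG_KO replicate 2 (0.0521). Car4, a carbonic anhydrase of the colon surface, stood at 59.4 ± 11.1 CPM against 943 ± 475 CPM, a log2 change of -3.97 (SE 0.42, edgeR adjusted p = 0.181). Of 16 enteroendocrine genes 15 were negative, with a median of -0.79, or -0.18 without ctr replicate 1 (camera adjusted p = 0.0254, adjusted p = 0.723 with an estimated correlation), a call lost without ctr replicate 1 (0.332), ctr replicate 3 (0.0693), PG_KO replicate 1 (0.0523) or PG_KO replicate 3 (0.0929). The drug efflux pump Abcb1a had the smallest edgeR adjusted p of all genes, 0.0770, at 17.2 ± 2.16 CPM against 61.4 ± 4.25 CPM and a log2 change of -1.83 (SE 0.14). Car4 and Abcb1a passed with DESeq2 (adjusted p = 1.91e-18 and 2.86e-22), and with edgeR without a low-count filter (adjusted p = 0.0289 for each) or without ctr replicate 3 (adjusted p = 0.0329 for each). The xenobiotic list that holds it, negative in 14 of 19 genes, did not pass (camera adjusted p = 0.0713), although 6 of its genes passed adjusted over the list alone, 5 of them lower. Camera called it, lower, without ctr replicate 1 (adjusted p = 1.19e-04), ctr replicate 2 (0.0480) or PG_KO replicate 1 (0.0209). With the mean expression of smooth muscle, fibroblast and endothelial genes per library as a stromal covariate, chosen after the data were seen, the enteroendocrine median was -0.11 and its call was lost (camera adjusted p = 0.626). The goblet median was -1.77, the antimicrobial -1.46, the Paneth -1.23 and the colonocyte -0.88, and these 4 stayed called (camera adjusted p = 7.69e-17, 5.11e-08, 0.00398 and 1.78e-07), while xenobiotic genes were called lower at -0.85 (camera adjusted p = 5.27e-05). Single genes moved more, as the enteroendocrine genes Pyy from -1.35 to -0.066 and Isl1 from -1.26 to -0.46 and the Paneth cell gene Mptx1 from -4.26 to -1.23. Leaving out ctr replicate 1 alone, without the covariate, gave -0.42 for Pyy, -0.64 for Isl1 and -4.11 for Mptx1. The stromal covariate stood at 7.07 and 6.47 in ctr replicates 1 and 2. It was 4.82 in ctr replicate 3 and 4.81 to 5.25 in PG_KO libraries. Values with the covariate therefore rest largely on ctr replicate 3, and camera with an estimated correlation was not run with it.

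The T and NK cell list had a camera adjusted p of 1.07e-07 (adjusted p = 0.487 with an estimated correlation), with 12 of 13 genes past the edgeR test adjusted over the list alone. Cd28, a costimulatory receptor of T cells, stood at 0.594 ± 0.255 CPM against 2.03 ± 0.493 CPM (edgeR adjusted p = 0.330, DESeq2 adjusted p = 0.0235). The B and plasma cell list was negative in 11 of 11 genes with a median of -1.67 (camera adjusted p = 1.23e-04, adjusted p = 0.723 with an estimated correlation). Smooth muscle genes were negative in 12 of 12 cases with a median of -1.53, and fibroblast genes in 12 of 12 with a median of -1.11 (camera adjusted p = 0.00154 for each, adjusted p = 0.723 with an estimated correlation). For smooth muscle this rested on ctr replicates 1 and 2, at a mean log2 CPM of 8.48 and 8.17, while ctr replicate 3, at 5.94, lay among the PG_KO libraries, at 5.93, 6.27 and 6.69. Endothelial genes had a median of -1.30, or -0.75 without ctr replicate 1 (camera adjusted p = 0.0118, adjusted p = 0.723 with an estimated correlation) and macrophage genes a median of -0.80, with -0.18 without ctr replicate 1, -1.33 without PG_KO replicate 1 and -0.41 without PG_KO replicate 3 (camera adjusted p = 0.0149, adjusted p = 0.731 with an estimated correlation). The endothelial and macrophage calls were lost without ctr replicate 1 (camera adjusted p = 0.0845 and 0.209) or PG_KO replicate 3 (0.0929 and 0.443). Enteric neurons and glia (camera adjusted p = 0.0637), neutrophils (0.0826) and tuft cells (0.172) did not pass with all 6 libraries. Neurons and glia were called lower without ctr replicate 3 (6.61e-04) or PG_KO replicate 1 (0.0209), tuft cells without ctr replicate 3 (0.0205), and neutrophils without ctr replicate 2 (0.00483), PG_KO replicate 1 (0.0140) or PG_KO replicate 2 (0.0301). With the stromal covariate the T and NK cell median was -1.03 and the B and plasma cell median -0.89, both still called (camera adjusted p = 4.25e-06 and 0.00238), and the macrophage call was lost (camera adjusted p = 0.847).

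On the higher side in PG_KO, the cell cycle list had a camera adjusted p of 3.74e-10 (adjusted p = 0.723 with an estimated correlation), with the survivin gene Birc5 at 144 ± 23.2 CPM against 89.6 ± 18.5 CPM, and 0 genes past the edgeR test adjusted over the list alone. Desmosome genes other than Jup were positive in 10 of 10 cases with a median of 0.46 (camera adjusted p = 8.94e-04), cholesterol synthesis genes in 19 of 20 with a median of 0.42 (camera adjusted p = 9.61e-04) and intestinal keratins in 6 of 7 with a median of 0.66 (camera adjusted p = 0.0155), each with adjusted p = 0.723 with an estimated correlation. Without ctr replicate 3 these 3 medians were 0.79, 0.65 and 0.99, and the cholesterol median was 0.19 without ctr replicate 1 and 0.64 without PG_KO replicate 1. The stromal covariate lowered the medians of these 3 lists and of the cell cycle list. Cell cycle genes stayed called at 0.29 (camera adjusted p = 4.04e-05), whereas desmosome genes at 0.13 (camera adjusted p = 0.413), cholesterol genes at 0.097 (camera adjusted p = 0.690) and keratins at 0.25 (camera adjusted p = 0.279) did not. Camera no longer called keratins without PG_KO replicate 1 (adjusted p = 0.101) or cholesterol synthesis without ctr replicate 1 (0.0765). The plaque protein Ppl stood at 24.5 ± 4.14 CPM against 12.3 ± 6.90 CPM (edgeR adjusted p = 0.355). Its log2 change was 1.01, with 0.64 without ctr replicate 2 and 1.39 without ctr replicate 3. The lists named in the title of the series did not pass: p38 had a camera adjusted p of 0.526 with 10 of 26 genes positive, and the inflammasome 0.950 with 16 of 25 positive. The ATP receptor P2rx7, which triggers inflammasome assembly, stood at 7.25 ± 1.01 CPM against 19.0 ± 11.9 CPM (edgeR adjusted p = 0.330, DESeq2 adjusted p = 0.0756). Its log2 change was -1.36 (SE 0.43), -0.78 without ctr replicate 1, -0.48 with the stromal covariate, and -1.63 without ctr replicate 3 (edgeR adjusted p = 0.0440). Cytokines and NF-kB targets (camera adjusted p = 0.249, median 0.28, although camera put them lower) and interferon response (0.616, median 0.04, camera also lower) did not pass, and neither did adherens and tight junctions (0.0533), enterocytes (0.0713), fetal-like and regenerative epithelium (0.356), immediate early genes (0.778), Wnt targets (0.778) or p53 targets (0.950). Single libraries set the sign of the inflammatory lists: cytokines were called lower without PG_KO replicate 1 (camera adjusted p = 4.65e-04, median -0.61) and higher without PG_KO replicate 3 (0.00174, median 0.75). Interferon genes were called lower without PG_KO replicate 1 (camera adjusted p = 9.08e-06, median -0.66) and higher without PG_KO replicate 2 (0.0397, median 0.39). Junctions were called higher without ctr replicate 3 (6.00e-04), PG_KO replicate 2 (0.0301) or PG_KO replicate 3 (0.0388), and fetal-like genes higher without PG_KO replicate 3 (0.0147). Enterocytes were called lower without ctr replicate 1 (0.0155), PG_KO replicate 1 (0.0242) or PG_KO replicate 3 (0.0348).

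**Figure D3:**
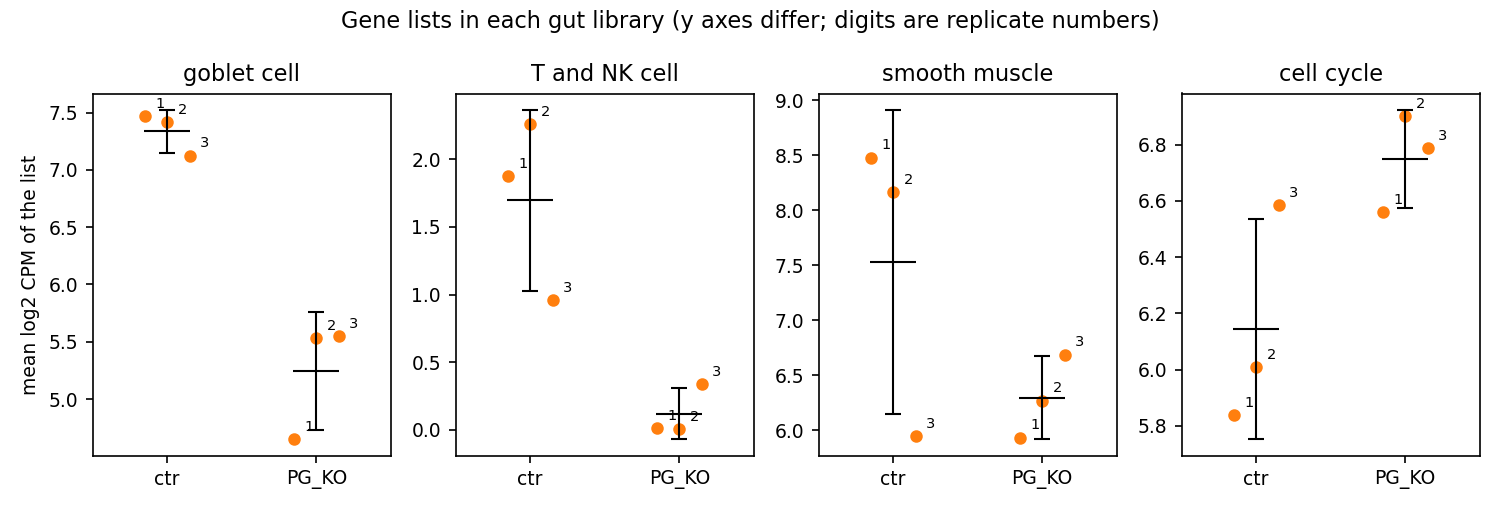
Mean log2 CPM (vertical axis) of the goblet cell, T and NK cell, smooth muscle and cell cycle lists in each gut library, with the mean and SD of 3 per group (horizontal axis) and digits for the replicate. Goblet cell scores of the groups do not overlap (4.65 to 5.55 against 7.12 to 7.47), while ctr replicate 3 lies with the PG_KO libraries for smooth muscle genes.

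With edgeR, 0 of 18043 genes passed in gut, while 2705 had an unadjusted p under 0.05 where chance gives 902. That count was 929 with the stromal covariate, which was chosen after the data were seen. It was 6568 without ctr replicate 3 and 1313 to 1823 without any other single library. DESeq2 called 458 genes, 91 higher and 367 lower, limma-voom called 0, edgeR without a low-count filter called 5, and edgeR without ctr replicate 3 called 1478, of which 374 were higher and 1104 lower. The groups did not overlap for 18.6% of genes, against 10% by chance. PG_KO replicate 3 held 11248 reads of Xist, the RNA of the inactive X chromosome, and 0 reads of the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y, unlike the other 5 gut libraries, which held at most 3 Xist reads and expressed the Y-linked genes. Leaving out that library together with ctr replicate 1, an alternative chosen after the data were seen, gave 0 edgeR calls, with 1248 genes at an unadjusted p under 0.05.

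The last question is whether low Jup goes with the same changes in gut and in organoids. For Jup itself the gut change minus the organoid change was 0.18 on the log2 scale (SE 0.22, edgeR adjusted p = 0.576). Goblet cell genes, in contrast, were lower in PG_KO gut libraries and higher in Tamoxifen organoids, but with an estimated correlation camera called neither (adjusted p = 0.327 and 0.208) nor their difference (adjusted p = 0.0559). Across the 15330 genes tested in both systems the Spearman correlation of the log2 changes was 0.145 against DMSO organoids and 0.0991 against nativ organoids, and genes are not independent replicates. Because edgeR called 0 genes in gut (2705 at an unadjusted p under 0.05), it gave 0 shared calls. With DESeq2 calls in both, 33 genes were higher in both systems where 29.5 would be met by chance (Fisher's exact test, two-sided p = 0.427), and 71 were lower in both where 67.8 would be met (p = 0.654). A further 135 moved in opposite directions, for which no chance count was computed and no test was run. In a single edgeR fit of gut, Tamoxifen and DMSO libraries the change differed between the systems for 6958 of 19141 genes, 3002 of them higher and 3956 lower in gut than in organoids. That fit gave gut and organoids a shared spread per gene, although their separate common dispersions were 0.121 and 0.0194. The error of the gut change may thus be understated, and the count too high. The organoid change also carries the difference of code and Cre. The gut change may carry DSS, which the titles place on the PG_KO libraries, and PG_KO replicate 3 differed in its sex genes. Neither change can therefore be assigned to low Jup.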

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

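Chosen after the results were seen were the interaction fit of gut and organoids, the random covariates, and the tests of DMSO exposure, place of origin, low Jup, non-epithelial tissue, DSS, colon position and a swapped ctr replicate 3, whereas the comparisons, lists and leave-one-out fits they draw on were planned.

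The change between groups differed between the systems: in the edgeR interaction fit, 6958 genes changed differently in gut (PG_KO against ctr) than in organoids (Tamoxifen against DMSO). The shared spread of that fit may understate the error of the gut change, so the count may be too high. On the organoid side code and Cre change along with treatment and Jup. On the gut side the titles place DSS colitis on the PG_KO libraries. The difference between the systems therefore cannot be assigned to low Jup. For 5 lists, camera called opposite directions in the 2 systems, with members lower in PG_KO gut and higher in Tamoxifen organoids. With an estimated correlation none of the 5 gut calls stood (camera adjusted p from 0.327 to 0.723), and of the organoid calls only that of enteroendocrine cells did (camera adjusted p = 0.0168). The rule that picked these 5 lists also required a called difference, so their camera p-values of the difference are small by selection and add no support. The median of the gut change minus the organoid change was -7.74 for goblet cells (camera adjusted p of the difference 2.74e-09, adjusted p = 0.0559 with an estimated correlation). It was -13.97 for Paneth cells, over 13 genes of which only 5 were tested in gut alone (camera adjusted p = 5.52e-09, adjusted p = 0.0132 with an estimated correlation) and -8.03 for enteroendocrine cells (camera adjusted p = 3.26e-09, adjusted p = 0.0836 with an estimated correlation). It was -8.17 for colonocytes (camera adjusted p = 1.61e-05, adjusted p = 0.299 with an estimated correlation) and -5.99 for epithelial antimicrobial defence (camera adjusted p = 6.69e-05, adjusted p = 0.142 with an estimated correlation). These are fitted values, and their size is set largely by genes near 0 reads in DMSO organoids. The antimicrobial list shares genes with the goblet and Paneth lists, so the 5 lists are not separate evidence.

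Tamoxifen and DMSO organoids differed in 10907 genes, and only 1 of the 10 splits of the 6 libraries, the real one, gave as many (highest other 0), although 10 splits are too few for a share under 0.05. DMSO exposure is argued against as the cause, because Tamoxifen organoids differed from nativ organoids in 11012 genes (1 of 10 splits, highest other 0). A different place of origin of the T41 and T75 cultures may contribute: all Hox genes together, which mark position along the gut, had 204 times the CPM in Tamoxifen organoids that they had in the higher of the T75 groups (41.1 to 46.4 against 0.0655 to 0.381 CPM). Gut libraries stood at 423 to 787 CPM, and the T75 libraries held only 2 to 11 Hox reads each. The T75 organoids therefore nearly lacked reads of these genes, whatever the cause. Low Jup stays open as a cause: of the genes changed over 2-fold in organoids 58.2% moved the same way in gut, namely 46.7% of those that rose and 70.5% of those that fell, which decides nothing. Code, Cre and treatment change together in this design, so place of origin and low Jup cannot be told apart.

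Goblet cell genes were lower in the PG_KO gut libraries, without overlap between the groups (list scores 4.65 to 5.55 against 7.12 to 7.47). More muscle and connective tissue in the ctr libraries is argued against as the cause, since it would dilute epithelial genes in ctr, whereas the goblet median in PG_KO was -2.26. DSS colitis in the PG_KO libraries only, as the titles read, could remove goblet cells but cannot be told apart from the group: the neutrophil list, which colitis should raise, differed by -0.71 in mean log2 CPM (SE 0.88), too imprecise to decide. Samples from different positions along the colon also remain possible, since Hox genes of the posterior groups differed by -0.18 in mean log2 CPM (SE 0.42), although the bound was made stricter after this value was seen, and the earlier bound would have counted it against this explanation. Low Jup, the biological explanation the design names, coincides with the labels and was not tested apart from them.

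Leaving out ctr replicate 3 raised the edgeR calls in gut from 0 to 1478. A swapped label is argued against for this library, because its Jup CPM was 5.98 times that of the highest PG_KO library. Less stromal and muscle tissue may set it apart, as its stromal score of 4.82 lay with the PG_KO libraries (4.81 to 5.25) and below the other ctr libraries (7.07 and 6.47). With that score as a covariate the fit without ctr replicate 3 gave 0 calls (1166 genes at an unadjusted p under 0.05), but 14 of 20 random covariates also gave 0, so the fit decides nothing. With all 6 gut libraries, 10 of 10 splits gave at least the real count of 0 calls (highest other 2), but 10 splits are too few for a share under 0.05, and a real count of 0 is met by every split whatever the data.

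Between DMSO and nativ organoids the real split gave 0 edgeR calls, as did all 10 splits (highest other 0). In the real split 2408 genes had an unadjusted p under 0.05, or 1198 in the fit of only the 6 libraries, and DESeq2 called 157. The 10 splits are too few for a share under 0.05, and a real count of 0 is met by every split whatever the data.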

How the results depend on the processing

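The stromal covariate, leaving out ctr replicate 1 with PG_KO replicate 3, and lists on library totals were chosen after the data were seen. Calls of both Tamoxifen comparisons were within 1.5 times the reported count in all 14 alternatives each, with 9753 to 10929 against DMSO and 9870 to 11512 against nativ when each library in turn was left out, and Jup stayed past the threshold in both. With the replicate number as a replicate block the calls were 10823, 10838, 0 (DMSO against nativ) and 0 (gut) and the called lists 13, 13, 4 and 17, while deviations of same-number libraries correlated at -0.12 to 0.19 in organoids and -0.18 to 0.29 in gut, so a pairing by number was not apparent. DESeq2 called 157 genes between DMSO and nativ organoids and 458 in gut, no low-count filter 2 and 5, and leaving out 1 library 0 to 1 and 0 to 1478. The stromal covariate called 1 gene in gut. Gut Jup passed at -2.28 with DESeq2, at -2.27 without a filter and at -2.61 with the covariate, and ranged from -2.47 to -2.03 without single libraries, passing only without ctr replicate 3. With an estimated correlation 2, 2, 0 and 0 lists were called, and fry called 23 against nativ, 0 between DMSO and nativ and 2 in gut. DESeq2 gave 104 shared calls of gut and organoids.

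In gut the covariate, which is built from the muscle, fibroblast and endothelium lists, turned the medians of smooth muscle (0.032), endothelium (0.042), enteric neurons and glia (0.43) and adherens and tight junctions (-0.13). Medians of lists called in neither fit turned too, for neutrophils (0.097), immediate early genes (0.11), Wnt targets (0.017), the inflammasome (-0.25) and p53 targets (-0.12). The macrophage list lost its call, and its median turned to 0.065. Leaving out ctr replicate 1 with PG_KO replicate 3 gave 0.83 for cytokines, 0.18 for macrophages and 0.61 for neutrophils. Without single libraries cytokines ranged from -0.61 to 0.75 and interferon genes from -0.66 to 0.39. The cause was not tested for any other of these changes. The camera direction of a gut list changed, with a call in at least 1 of the fits, in 9 results. A further 290 kept their side of the threshold and, where called, their direction, while 52 lost the call and 26 gained one. Of the single gut genes 829 kept their side of the threshold and 38 gained a call. Direction was not compared where neither fit gave a call. Rsad2 went from 1.31 to -0.47 without PG_KO replicate 1, and with the stromal covariate Nkd1 went from -1.45 to 0.098, Nos1 from -1.24 to 0.21 and Pecam1 from -1.34 to 0.042. At the spread of these gut libraries, edgeR recovered 8% of simulated changes of 1 on the log2 scale, so a missed call in gut is weak evidence of no change.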

Other observations

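Of the tests reported here, the one on duct genes was chosen before its result was seen, and the genes named were chosen after their values were seen.

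Several transcription factors tied to regional identity, which were not tested as a list, differed between Tamoxifen and DMSO organoids. Cdx2, a master regulator of intestinal identity, stood at a mean of 329 CPM in Tamoxifen and 16.3 CPM in DMSO organoids (log2 change 4.27, SE 0.12). Its relative Cdx1 stood at 103 ± 5.45 CPM (SD, n = 3) against 1 read (ratio 8804, 95% counting interval 1579.8 to 347786). Gata4, which marks the proximal small intestine, changed by 10.84 (SE 0.53), Hnf4g by 9.37 (SE 0.24) and Hnf4a by 2.41 (SE 0.16). Isx, an intestinal homeobox gene, stood at 62.0 ± 0.588 CPM against 0 reads, at least 1762-fold higher, and sucrase-isomaltase, Sis, changed by 14.98 (SE 1.04). Higher in DMSO organoids were Sox17, at 33.2 ± 4.73 CPM against 2 reads (ratio 1472, interval 407 to 12159), Onecut1 (ratio 619, interval 212 to 3005), Pdx1 at -3.70 (SE 0.17) and Foxa2 at -4.48 (SE 0.13). All of these passed the edgeR test.

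The pattern of Sox17, Onecut1 and Pdx1, with few reads of intestinal position genes, led to the hypothesis that the T75 organoids may be epithelium of bile or pancreatic ducts. A list of 12 duct genes was written before they were looked up, and 11 were tested. Their median log2 change, Tamoxifen minus DMSO, was -0.13, with 5 genes higher and 4 lower in Tamoxifen, so the list did not decide. Pkhd1 (-7.32), Hhex (-5.98), Cys1 (-9.76) and Glis3 (-6.27) were lower in Tamoxifen organoids, while Tm4sf4 (1.72) and Ggt1 (3.89) were higher. The labels call all organoids products of mouse gut.

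In gut, the basal keratin Krt14 stood at a mean of 32.4 CPM (2701 reads) in PG_KO and 2.02 CPM (161 reads) in ctr libraries, without overlap (log2 change 4.02, SE 0.56), and did not pass the edgeR test. Clca1, a goblet cell secretory protein, changed by -4.52 (SE 0.82) and Zg16, a lectin of the mucus layer, by -3.02 (SE 0.73), neither past the edgeR test over all genes. The epithelial genes Epcam at 0.19 (SE 0.20) and Cdh1 at 0.16 (SE 0.21) differed by less than their errors. All 9 organoid libraries held at most 3 Xist reads and at least 1067 reads of Ddx3y.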
